A study of Mus musculus with 12 samples.

How the data were processed

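Single mouse embryos were collected at embryonic day 7.0, when gastrulation is under way, without treatment, in the C57BL/6J strain. RNA from 5 female and 7 male embryos of 7 litters was made into libraries with a kit for very low RNA input and the Nextera XT kit, pooled and sequenced as read pairs, per the labels' protocols. Each embryo was 1 animal, and each library was 1 replicate. Both sexes were present in litters 3, 6 and 9 alone.

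The submitters' processing notes name cutadapt 4.1, STAR 2.7.7a, Salmon 1.5.2 and DESeq2 1.34.0 and the mm10 build. How these tools were set is not given in the sources used here. A table of 55291 genes was used. Its 12 columns per embryo hold log2-scale values deposited by the authors, which the values show to be variance-stabilized with a floor of 10.4141. A mean signal per gene, deposited by the authors, is on the scale of normalized counts. The authors also deposited a log2 fold change of female over male with its standard error, a p-value and an adjusted p-value per gene. These last columns were used only as the authors' values.

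The transformation was inverted with its closed form to give a normalized count per gene and embryo. For 25183 of the 25451 genes with a mean above 0 (98.95%), the mean of the 12 inverted values equalled the deposited mean within a relative tolerance of 1e-06. For 525 genes, 257 of them with a deposited mean of 0, the inverted mean was above the deposited one. In 524 of the 525, setting the highest male value to the 20% trimmed mean of the 12 embryos gave the deposited mean within 1 normalized count summed over embryos, and setting the highest female value so explained none of the others. Whole reads could not be recovered: between 78.25% and 81.97% of low values per library lay within 0.1 of a whole multiple of the most common low value. No count model was therefore used. Taking that most common low value as 1 fragment, the libraries held between 83 and 114.4 fragments in units of 1000000. Intervals and floors cover counting error only, since amplified fragments are not independent molecules. The confidence level was 95%, and the floor was 3 fragments per library.

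Chromosomes came from GENCODE M21 gene symbols for 53292 genes, from symbol synonyms for 406 and from a RefSeq gene table of the same GRCm38 assembly for 679. The 920 symbols without a single chromosome were left in no chromosome class. Of these, 6 matched GENCODE on several chromosomes and are also counted among the matches above. Coordinates are GRCm38 (mm10), counted from 1.

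Sex was compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(normalized count + 1), with sex as the only term and all 12 embryos. Genes with a normalized count of at least 10 in at least 5 embryos were tested, which left 16455. Fold changes are on the log2(count + 1) scale, which understates changes of low genes. P-values were two-sided and adjusted by Benjamini-Hochberg, with 0.05 as the threshold. This test, for values normalized per embryo, was fixed before the data were examined. The filter and the inversion of the transformation were chosen after the table was seen and before any fit, and the authors' calls were known when later alternatives and gene lists were added.

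The 24 gene lists were fixed before the data were examined and tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. A list's level in an embryo was the mean of its members' log2 values relative to the 12 embryos, and sexes were compared over all 792 splits of the embryos into 5 and 7. The smallest p this allows is 0.00126. The same exact permutation test was used for the median level of X-linked minus autosomal genes, with Xist left out. Litters were compared by the mean Spearman correlation of pairs within and between litters, with 100000 permutations of the litter labels.

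Named genes followed a rule fixed before the data were examined: Xist, the members of the Y-linked, X-inactivation centre and escape lists past the threshold, with Kdm5c, Kdm6a, Ddx3x and Eif2s3x in any case; up to 10 autosomal genes past the threshold per direction by size; up to 10 other X-linked genes past it; and per list the members past it or, where none passed, up to 3 of the highest mean level, of which up to 2 are given. Members past the threshold when adjusted over the list alone, and list members named from the authors' deposited table, were chosen after their values were seen, as were Tppp3, Dnaic2, Lad1 and Ly6g6c. The result of 1 list member is not reported here.

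The fit was tested on simulated data with the means, spread and depth of these libraries and known folds. Among 16111 genes tested, 44.3% of 79 genes changed 1.5-fold, 66.2% of 80 changed 2-fold and 75.0% of 40 changed 4-fold were called, all 118 with the right sign, beside 6 false calls. The changed genes were drawn above a minimum mean level, X-linked genes and a random set were raised as well, and genes varied independently. With so many changed genes the adjusted threshold is looser than in the real fit, where 7 genes passed. These shares therefore do not give the power of the real comparison. Alternatives covered normalization, filter, pseudocount, array weights, litter and replicate number as terms, thresholds, and leaving out each embryo. Limma on the deposited log2-scale values, a robust fit, the authors' deposited calls and fits without 2 pairs of libraries were added after the data were seen.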

Results

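Transcript levels were measured in 12 whole embryos at embryonic day 7.0, 5 female and 7 male. The comparison asked whether the sexes differ in expression before any exposure, at the stage at which the series studied alcohol-induced craniofacial malformation. In units of 1000000 fragments, female libraries held 91.8 ± 5.46 (SD, n = 5) and male libraries 98.2 ± 10.3 (SD, n = 7), as estimated from the value of 1 fragment. Mitochondrial transcripts made up 0.587% ± 0.079 (SD, n = 5) of the normalized counts in female and 0.648% ± 0.125 (SD, n = 7) in male embryos. Embryos resembled one another closely, with Spearman correlations over genes from 0.972 to 0.984 over all pairs.

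Xist, the noncoding RNA that coats the inactive X chromosome, and the Y-linked genes matched the labelled sex in every embryo. Xist was between 109 and 560.7 normalized counts in the 5 females and between 0 and 38.6 in the 7 males, the highest male being replicate 6. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty averaged 3764 ± 240.3, 3037 ± 455, 1096 ± 178 and 2156 ± 430.5 normalized counts (SD, n = 7) in males. Female libraries held few of these transcripts, with 83.2 for Ddx3y and 40.5 for Uty in replicate 5, 32.6 for Ddx3y in replicate 4 and 18.8 for Eif2s3y in replicate 1. Ddx3y can share reads with its X-linked copy Ddx3x, and likewise Uty with Kdm6a. Usp9y and Zfy1 averaged 3.07 and 1.02 in males, and Uba1y, Zfy2 and Sry were at 0 in all 12 embryos.

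**Figure D1:**
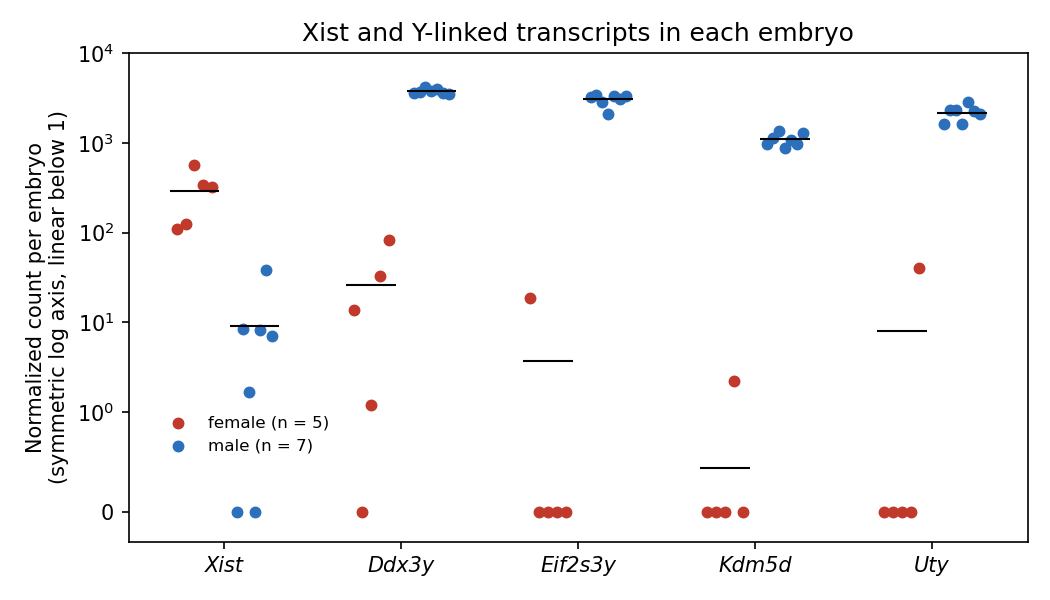
Normalized counts of Xist and 4 Y-linked genes in each embryo, on a symmetric log axis that is linear below 1; points are embryos (5 female, 7 male) and bars are means. All 5 females lie above all 7 males for Xist, and all 7 males lie above all 5 females for the Y-linked genes.

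Beyond the Y chromosome, 3 genes differed between the sexes, and each was higher in females. Eif2s3x, an X-linked translation initiation factor subunit that escapes X inactivation, was at 7297 ± 479.2 normalized counts in females (SD, n = 5) and 4687 ± 370.2 in males (SD, n = 7). Its log2 fold change was 0.64 (SE 0.07, adjusted p = 0.000734 by limma), and all 5 females lay above all males. Xist rose by 5.61 on the log2 scale (SE 0.89, adjusted p = 0.0431 by limma), from 9.13 ± 13.5 (SD, n = 7) to 290.4 ± 185.1 (SD, n = 5). Esr2, which encodes estrogen receptor beta, was at 29 ± 14.1 in females (SD, n = 5) and at 0 in all 7 males, at least 9.91-fold higher against a floor of 3 fragments per library (adjusted p = 0.0474 by limma). The Y-linked genes had log2 fold changes of -8.58 (Ddx3y, SE 0.835), -10.69 (Eif2s3y, SE 0.64), -9.75 (Kdm5d, SE 0.37) and -9.97 (Uty, SE 0.78). Kdm5d rested on 2 fragments in 1 female library, a male to female ratio of 2630 with a 95% counting interval of 727 to 21700.

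These genes lie on GRCm38 at X from 94188707 to 94212862 (Eif2s3x), X from 103460366 to 103483254 (Xist), 12 from 76120419 to 76177259 (Esr2), Y from 897788 to 956786 (Kdm5d), Y from 1010543 to 1028847 (Eif2s3y), Y from 1096861 to 1245759 (Uty) and Y from 1260771 to 1286629 (Ddx3y). In all, 7 of 16455 genes passed, 3 higher and 4 lower in females, of which 1 of 15809 was autosomal and 2 of 577 were X-linked. No autosomal gene was lower in females past the threshold by limma, while 852 were at an unadjusted p below 0.05 and 112 in the authors' deposited table. The single autosomal call depended on the setting: with a pseudocount of 0.1 it was Dnaic2, lower in females, in place of Esr2, and without female replicates 1, 3 or 5 or male replicate 4 it was 1 gene lower in females each time. Esr2 lost its call without any 1 of the 12 embryos (adjusted p from 0.0603 to 0.22), and Xist without any 1 of 10 embryos (all but male replicates 1 and 6; adjusted p up to 0.205). With litter as a fixed block, which left 4 residual degrees of freedom in place of 10, the 4 Y-linked genes alone passed. That fit compares the sexes only within the litters that held both, so fewer embryos inform it and a lost call need not reflect litter. The log2 fold change was then 0.63 (SE 0.09, adjusted p = 0.23 by limma) for Eif2s3x and 4.85 (SE 0.80, adjusted p = 0.283 by limma) for Xist.

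The authors' deposited table holds 214 genes at an adjusted p below 0.05, 84 higher and 130 lower in females, of which 189 are autosomal, 20 X-linked and 5 Y-linked. All 7 genes called by limma are among them. Of the 200 deposited calls tested by limma, 200 had the same sign, and 199 had an unadjusted p below 0.05. Members of the fixed lists in the authors' deposited table include Tsix and Ftx with Xist, Kdm6a, Kdm5c and Pbdc1 with Eif2s3x, Trf, Afp, Dppa4 and Wnt7b higher in females, and Msgn1 lower.

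Genes that escape X inactivation passed as a list, toward higher levels in females, by camera with the preset correlation. Of 11 members tested, 7 had positive log2 fold changes, 1 rose past the threshold and none fell, and 4 rose when adjusted over the list alone (Eif2s3x, Pbdc1, Kdm6a and Kdm5c). Kdm6a, a histone demethylase, was at 4062 ± 834 in females (SD, n = 5) and 2736 ± 343.8 in males (SD, n = 7), and Kdm5c, another, at 9118 ± 1204 (SD, n = 5) and 7251 ± 505.2 (SD, n = 7). Their log2 fold changes were 0.55 (SE 0.13, adjusted p = 0.2 by limma) and 0.32 (SE 0.08, adjusted p = 0.215 by limma). Ddx3x, an RNA helicase, was at 16650 ± 1489 (SD, n = 5) and 17060 ± 2614 (SD, n = 7), with a log2 fold change of -0.03 (SE 0.10). The list's median log2 fold change was 0.11 (camera adjusted p = 0.000733; adjusted p = 0.0717 with an estimated correlation; 0.149 with litter as a fixed block). The exact permutation p of the list mean was 0.0568, and 0.227 when adjusted over the 24 lists, while fry gave an adjusted p of 0.00631. Among 7 members tested of the X-inactivation centre, 1 rose, and 3 rose when adjusted over the list alone (Xist, Tsix and Ftx; camera adjusted p = 0.000374, and adjusted p = 0.0222 with an estimated correlation). Tsix overlaps Xist on the other strand, and the counting is not stated to use strand, so reads of the pair cannot be told apart. All 4 Y-linked members tested fell (camera adjusted p = 1.86e-23; adjusted p = 6.62e-05 with an estimated correlation). Of 10 X-linked imprinted or clustered reproductive genes none passed (camera adjusted p = 0.978). Rhox5, a homeobox gene, was at 10410 ± 1360 (SD, n = 5) and 10120 ± 1774 (SD, n = 7), and Xlr3a at 2005 ± 339.8 (SD, n = 5) and 1773 ± 387.2 (SD, n = 7).

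Over the whole chromosome, X-linked genes were slightly lower in females. The median log2 level of 576 X-linked genes minus that of 15809 autosomal genes was -0.16 ± 0.06 in females (SD, n = 5) and -0.04 ± 0.07 in males (SD, n = 7). The difference of -0.12 had p = 0.0164 in the two-sided exact permutation test. The median log2 fold change was -0.04 for X-linked and 0.00 for autosomal genes, and 241 of the 576 X-linked genes (41.8%) had a positive one, against 50.1% of autosomal genes. At an unadjusted p below 0.05, 68 X-linked genes were lower and 20 higher in females, Xist left out. Among genes with a mean level of at least 100 the difference in median level was -0.056, with exact permutation p = 0.169. The median log2 fold change, X-linked minus autosomal, was -0.043 over all genes tested and -0.049 among these.

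**Figure D2:**
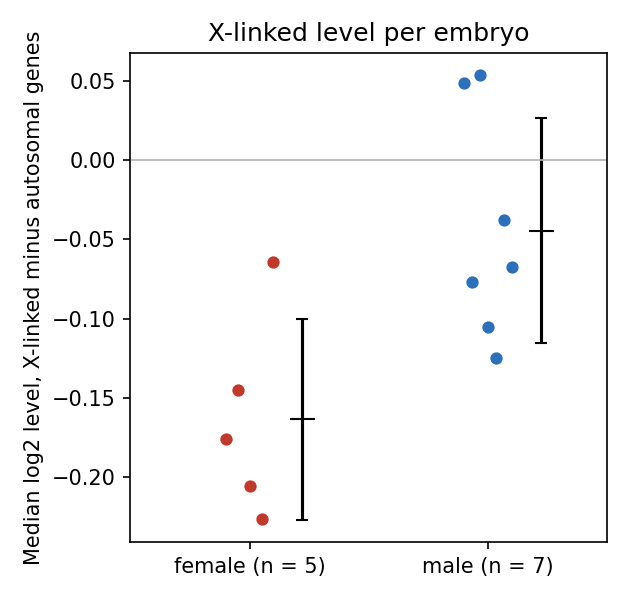
Median log2 level of X-linked minus autosomal genes in each embryo; points are embryos, and the bar beside each group is the mean ± SD (5 female, 7 male). The female mean of -0.16 lies below the male mean of -0.04, with overlapping ranges.

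Visceral endoderm genes, which mark the extraembryonic layer that surrounds the epiblast, passed toward higher levels in females by camera with the preset correlation. All 19 members had positive log2 fold changes, from 0.25 to 0.98 with a median of 0.51. The list mean lay between 0.13 and 0.59 in females and at 0.31, 0.18 and 0.29 in male replicates 1, 3 and 4, inside the female range. It was at -0.79, -0.60, -0.66 and -0.29 in male replicates 2, 5, 6 and 7, so the difference rests on these males. None passed over all genes, and 9 rose when adjusted over the list alone (Trf, Afp, Apoa4, Amn, Apoe, Apoa2, Spp2, Hnf4a and Apoa1). Apoe, an apolipoprotein, was at 134400 ± 18060 in females (SD, n = 5) and 107500 ± 20160 in males (SD, n = 7). Trf, which encodes transferrin, was at 10830 ± 1871 in females (SD, n = 5) and 7112 ± 1088 in males (SD, n = 7), with all females above all males. Afp, alpha-fetoprotein, was at 15530 ± 907.8 (SD, n = 5) and 10380 ± 2529 (SD, n = 7), and Apoa1, another apolipoprotein, at 126300 ± 20640 (SD, n = 5) and 84370 ± 34580 (SD, n = 7). The camera adjusted p was 2.43e-12, and adjusted p = 0.335 with an estimated correlation. The exact permutation p was 0.0492, and 0.227 when adjusted over the lists. Afp passed over all genes without male replicate 1 (adjusted p = 0.0328 by limma).

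Trophoblast and extraembryonic ectoderm genes passed toward lower levels in females by camera with the preset correlation. Positive log2 fold changes were seen for 2 of the 14 members tested, and the others were lower in females. Of 14 tested, none passed over all genes; adjusted over the list alone, Krt8 and Prl3d1 fell and Wnt7b rose. Krt8, a keratin of simple epithelia, was at 41230 ± 2547 (SD, n = 5) and 50130 ± 6492 (SD, n = 7). Prl3d1, a placental lactogen of trophoblast giant cells, was at 7099 ± 5809 (SD, n = 5) and 24250 ± 16630 (SD, n = 7). Wnt7b was at 473.7 ± 331.2 (SD, n = 5) and 92.4 ± 40.7 (SD, n = 7). The median was -0.39 (camera adjusted p = 0.0121; adjusted p = 0.615 with an estimated correlation; exact permutation p = 0.181, adjusted 0.366), and the call was lost without female replicate 2 (0.0569) or male replicate 5 (0.0655). Maternal decidual genes did not pass (13 tested, camera adjusted p = 0.717), with Prl8a2, a decidual prolactin-family gene, at 9144 ± 6705 (SD, n = 5) and 18550 ± 12320 (SD, n = 7), and Cryab at 1651 ± 1030 (SD, n = 5) and 1946 ± 590.8 (SD, n = 7). Adult blood genes did not pass (9 tested, camera adjusted p = 0.908). Their adult globins Hba-a1, at 2078 ± 1398 (SD, n = 5) and 1740 ± 1076 (SD, n = 7), and Hbb-bs, at 1292 ± 840.6 (SD, n = 5) and 1152 ± 618 (SD, n = 7), varied widely within each sex. Without female replicate 3 the list was higher in females (median 0.68, camera adjusted p = 0.0422). Parietal endoderm genes did not pass (12 tested, camera adjusted p = 0.843), with Ctsl at 42670 ± 4727 (SD, n = 5) and 38110 ± 8537 (SD, n = 7). Without female replicate 5 that list was lower in females (median -0.58, camera adjusted p = 0.00109), and without male replicate 4 the median was 0.13 (camera adjusted p = 0.714). Its member Lamb1 was at 47040 in that female and at 46850 in that male, against 9943 to 18770 in the other males and 10960 to 13530 in the other females.

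Of the embryonic lineages, the epiblast and pluripotency list alone passed, toward higher levels in females and by camera with the preset correlation. None of its 16 members passed singly, and 11 had positive log2 fold changes. The median was 0.06, in a range from -0.27 to 3.43. The list mean was 0.32 higher in females, a difference that the member at 3.43 raises. The camera adjusted p was 0.0454, with adjusted p = 0.615 with an estimated correlation and an exact permutation p of 0.0366, adjusted 0.22. Dnmt3b, a de novo DNA methyltransferase, was at 213200 ± 16490 (SD, n = 5) and 198000 ± 23110 (SD, n = 7), and Pim2 at 97790 ± 5726 (SD, n = 5) and 98730 ± 12960 (SD, n = 7). The call was lost without any 1 of 8 embryos (female replicates 1, 2 and 4 and male replicates 2, 3, 4, 5 and 7; adjusted p up to 0.214) and with litter as a fixed block (0.149). None of the 18 primitive streak and nascent mesoderm genes passed (camera adjusted p = 0.978). Lefty2 was at 30070 ± 2241 (SD, n = 5) and 36700 ± 7049 (SD, n = 7), and Eomes, a T-box factor of the streak, at 23200 ± 1941 (SD, n = 5) and 15810 ± 7164 (SD, n = 7). None of the 12 genes of node, anterior mesendoderm and definitive endoderm passed (camera adjusted p = 0.757), with Cer1 at 25050 ± 4984 (SD, n = 5) and 33330 ± 12190 (SD, n = 7) and Sox17 at 17110 ± 1117 (SD, n = 5) and 16630 ± 1588 (SD, n = 7). None of the 11 extraembryonic mesoderm and blood progenitor genes passed (camera adjusted p = 0.104), with Hand1 at 4438 ± 863.9 (SD, n = 5) and 5942 ± 2330 (SD, n = 7) and Kdr at 5768 ± 1013 (SD, n = 5) and 4042 ± 1621 (SD, n = 7). That list passed without male replicate 1 (median 0.69, camera adjusted p = 0.0372).

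**Figure D3:**
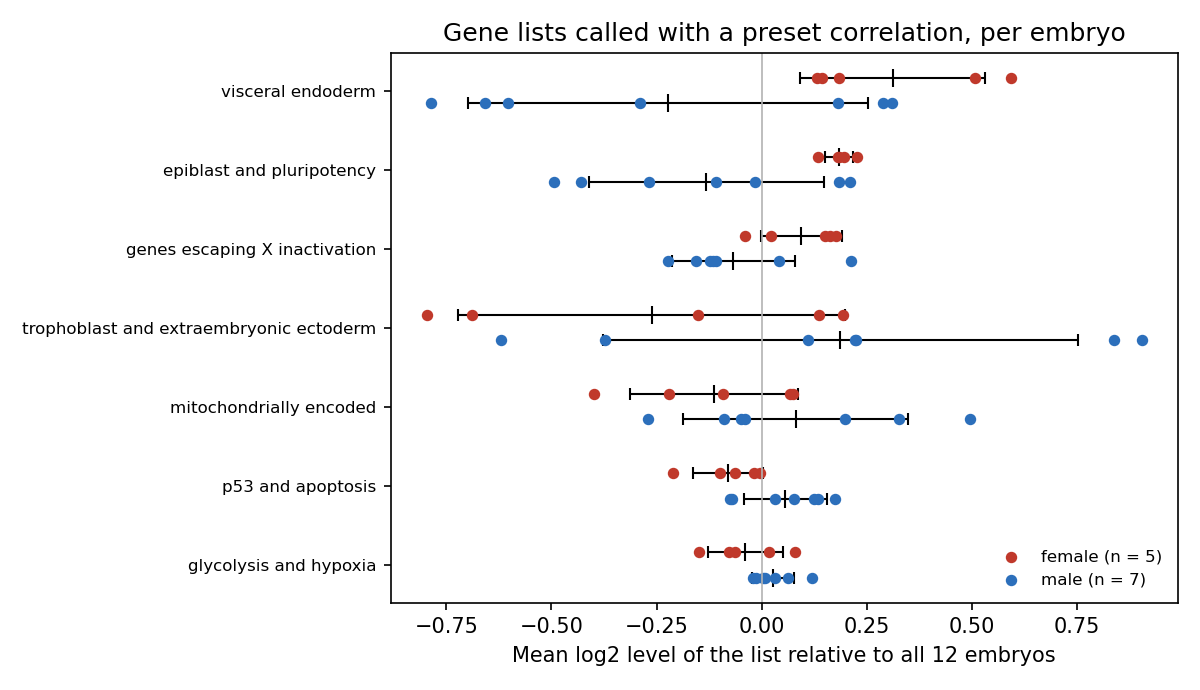
Mean log2 level of 7 gene lists in each embryo, relative to all 12 embryos, for the lists past the threshold at a preset correlation apart from the Y-linked and X-inactivation centre lists; points are embryos, and bars are the mean ± SD (5 female, 7 male). The sexes overlap for each of the 7 lists; the visceral endoderm mean is 0.53 higher in females.

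Among lists tied to alcohol exposure and its targets, the p53 and apoptosis list passed toward lower levels in females by camera with the preset correlation. Of 17 members tested none passed over all genes. Trp53, the transcription factor p53, was at 23020 ± 1264 (SD, n = 5) and 22800 ± 1697 (SD, n = 7), and Bax at 12970 ± 731.1 (SD, n = 5) and 14970 ± 2102 (SD, n = 7). The median was -0.11 (camera adjusted p = 0.0346; adjusted p = 0.44 with an estimated correlation; exact permutation p = 0.0366, adjusted 0.22), and the call was lost without female replicate 4 or male replicates 2, 5 or 6 (adjusted p up to 0.112) and with litter as a fixed block (0.0573). None of the 15 Hedgehog pathway genes passed (camera adjusted p = 0.584), with Smo at 10270 ± 921.4 (SD, n = 5) and 11480 ± 2224 (SD, n = 7) and Sufu at 6604 ± 502.2 (SD, n = 5) and 6030 ± 749.6 (SD, n = 7). None of the 8 alcohol and aldehyde metabolism genes tested passed (camera adjusted p = 0.863), with Adh5, an alcohol dehydrogenase, at 36040 ± 2995 (SD, n = 5) and 37560 ± 2340 (SD, n = 7), and Aldh7a1 at 17080 ± 935 (SD, n = 5) and 16190 ± 1108 (SD, n = 7).

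Of 17 retinoic acid genes none passed over all genes (camera adjusted p = 0.376). Aldh1a3, a retinaldehyde dehydrogenase, rose when adjusted over the list alone, from 5.17 ± 9.31 (SD, n = 7) to 43 ± 18 (SD, n = 5), while Cyp26a1, which degrades retinoic acid, was at 23810 ± 1204 (SD, n = 5) and 18780 ± 6393 (SD, n = 7) and Rxrb at 6279 ± 626.1 (SD, n = 5) and 5554 ± 626.7 (SD, n = 7). None of the 16 antioxidant genes passed (camera adjusted p = 0.909), with Prdx1 at 183800 ± 20180 (SD, n = 5) and 234900 ± 45520 (SD, n = 7) and Gpx1 at 78130 ± 3593 (SD, n = 5) and 73910 ± 3491 (SD, n = 7). None of the 20 Nodal, BMP and Wnt pathway genes passed (camera adjusted p = 0.717), with Ctnnb1 at 49510 ± 4323 (SD, n = 5) and 53260 ± 6803 (SD, n = 7) and Id3 at 33900 ± 3089 (SD, n = 5) and 33040 ± 4406 (SD, n = 7).

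Glycolysis and hypoxia genes passed toward lower levels in females by camera with the preset correlation, by a small amount. Of 15 tested none passed over all genes, and Pgk1, which is X-linked, and Bnip3, which is autosomal, fell when adjusted over the list alone. Ldha, lactate dehydrogenase A, was at 853500 ± 50340 (SD, n = 5) and 912000 ± 33330 (SD, n = 7), and Pkm, pyruvate kinase, at 650500 ± 34600 (SD, n = 5) and 674300 ± 27870 (SD, n = 7). The median was -0.07 (camera adjusted p = 0.00537; adjusted p = 0.44 with an estimated correlation; exact permutation p = 0.133, adjusted 0.366), and the call was lost without female replicate 5 (0.0704). Of 13 mitochondrially encoded genes, only 7 were above the filter and tested. All 7 had negative log2 fold changes, from -0.38 to -0.06 (camera adjusted p = 0.0135; adjusted p = 0.615 with an estimated correlation; exact permutation p = 0.201, adjusted 0.371). None passed singly, with mt-Cytb at 106800 ± 20280 (SD, n = 5) and 140100 ± 34470 (SD, n = 7) and mt-Nd1 at 150200 ± 23060 (SD, n = 5) and 158400 ± 23210 (SD, n = 7). That call was lost without female replicate 4 or male replicates 1 or 7 (adjusted p up to 0.177) and with litter as a fixed block (0.0917). Cell cycle genes (14 tested, camera adjusted p = 0.978), epigenetic regulators (16 tested, 0.908) and genes of dissection stress (13 tested, 0.978) did not pass. Mcm2 was at 75650 ± 2411 (SD, n = 5) and 72330 ± 2579 (SD, n = 7), Mcm6 at 75450 ± 1947 (SD, n = 5) and 71430 ± 2758 (SD, n = 7), Hdac1 at 41140 ± 2602 (SD, n = 5) and 40760 ± 2857 (SD, n = 7), Ier2 at 10280 ± 177.9 (SD, n = 5) and 10380 ± 1192 (SD, n = 7) and Dusp1 at 3252 ± 239.8 (SD, n = 5) and 2753 ± 501.3 (SD, n = 7).

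In all, 9 of 24 lists passed with the preset correlation, 4 higher and 5 lower in females. With an estimated correlation 2 passed, the Y-linked and X-inactivation centre lists, as by the exact permutation test of the list means (adjusted p = 0.0152 for each), and fry called 3, these and the escape list. With litter as a fixed block 5 passed. Outside the sex chromosome lists 6 passed (visceral endoderm, trophoblast, epiblast, glycolysis, mitochondrial and p53), and 18 of 100 splits of the embryos into 5 and 7, the real one included, gave as many.

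Embryos of 1 litter did not test as more alike than embryos of different litters, in a comparison that did not hold sex fixed. Over autosomal genes the mean Spearman correlation was 0.9785 for the 7 pairs within a litter and 0.9782 for the 59 pairs between litters, a difference of 0.00032 (two-sided permutation p = 0.773). Most pairs within a litter join a female and a male. Over all genes tested, such pairs averaged 0.9769, against 0.9791 within females and 0.9787 within males. A litter effect may therefore be masked and stays open.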

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

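The tests on Y-linked transcripts in female libraries were chosen only after the result was seen. Of 192 groups of values looked at, 12 (6.2%) held an embryo far from the rest of its sex, where chance gives about 5%. Lamb1, a laminin chain of basement membranes, was at 47040 normalized counts in female replicate 5, against 10960 to 13530 in the other females, and at 46850 in male replicate 4, against 9943 to 18770 in the other males. Trf was at 14110 in female replicate 3, against 9553 to 10570 in the other females. Pbdc1 was at 18580 in female replicate 3, against 20830 to 21370, and Pkm at 589800 in female replicate 5, against 659200 to 677100. Eif2s3y was at 2101 in male replicate 4, against 2842 to 3373 in the other males. Xist was at 38.56 in male replicate 6, against 0 to 8.423 in the other males. The mean of the Hedgehog list was -0.749 in male replicate 1, against 0.0911 to 0.485, and that of the alcohol and aldehyde list was -0.379 in female replicate 1, against 0.171 to 0.31. Eif2s3y was at 18.82 in female replicate 1, Kdm5d at 2.213 in female replicate 4 and Uty at 40.49 in female replicate 5, with the other females at 0 for each.

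The Y-linked transcripts in female libraries were unevenly spread over genes. In female replicate 5 Ddx3y was at 2.21% and Uty at 1.88% of the male mean, while Eif2s3y and Kdm5d were at 0; in female replicate 1 Eif2s3y was at 19 fragments and Uty at 0. Carry-over between pooled libraries would bring the 4 genes in their male proportions, and the shares differed from these beyond counting error (Monte Carlo chi-square p = 1e-05, the smallest the resamples can give). Fragments of X-linked copies counted for the Y-linked gene would follow the copy, and the ratio of Ddx3y to Ddx3x differed between female libraries (Monte Carlo chi-square p = 1e-05, again the smallest possible). Both tests treated estimated fragments as independent, which amplified fragments are not, and Uty against Kdm6a was not tested. Neither carry-over nor sharing of reads is therefore excluded. Carry-over of a few molecules before amplification may still account for the uneven spread and was not tested, and no biological explanation was tested.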

How the results depend on the processing

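Limma on the deposited variance-stabilized values, a robust fit, the authors' comparison and the fits without 2 pairs of libraries (female replicate 5 with male replicate 6, and female replicates 2 and 3) were chosen after the data were seen. The cause of the changes given here was not tested. The count of 7 genes became 11 with array weights, 11 at an adjusted p below 0.1, 4 with litter as a fixed block, 214 in the authors' deposited table and 186 with the deposited p adjusted over all genes, and lay between 5 and 9 when each embryo was left out. The count of 1 autosomal gene became 0 with quantile normalization, with a mean level of at least 10, with litter as a fixed block and at an adjusted p below 0.01, 2 with no filter, with a pseudocount of 5 and without female replicates 2 and 3, 3 on the deposited variance-stabilized values, 5 with array weights and at an adjusted p below 0.1, and 189 and 164 with the deposited values as above. Leaving out each embryo gave 0 to 3 autosomal genes: 0 without female replicate 4 or male replicates 2, 5, 6 or 7, 2 without female replicate 2 and 3 without male replicate 1. The direction turned with it: 1 lower and 0 higher in females without female replicates 1, 3 or 5 or male replicate 4, without female replicate 5 and male replicate 6 together and with a pseudocount of 0.1 (Dnaic2), 2 lower and 0 higher without female replicates 2 and 3, and 2 lower and 1 higher without male replicate 1. The count of 2 X-linked genes became 1 with no filter, with a pseudocount of 0.1, at an adjusted p below 0.01, with a log2 fold change of at least 1 and without female replicates 2 and 3, 0 with litter as a fixed block, and 20 and 17 with the deposited values. It was 1 to 2 with each embryo left out, 2 only without male replicates 1 or 6. The X-linked minus autosomal difference in median level was -0.05639 with a mean level of at least 100, and -0.1439 to -0.1028 with each embryo left out. The count of 9 lists became 2 with an estimated correlation and 5 with litter as a fixed block, and was 6 to 10 with each embryo left out. Litter similarity stayed on its side of the threshold in both alternatives.

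Replicate numbers 1 to 5 are shared by the sexes but do not pair the embryos: the correlations of deviations were -0.068, -0.021, -0.037, -0.026 and 0.009, and no female correlated best with the male of its number. With the replicate number as a block, 4 genes passed, 0 of them autosomal and 0 X-linked, and 8 lists, with an adjusted p of 0.0773 for the p53 and apoptosis list.

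Of 67 genes followed through the settings, 55 kept their direction in every setting run. The other 12, none of them past the threshold, turned in some. Ddx3x had log2 fold changes of 0.002535 with array weights and 0.0265 with the replicate block, Ier2 of 0.00897, 0.01221 and, with litter as a fixed block, 0.003371, and Rhox5 of -0.022 with the replicate block. Hdac1 was at -0.0008139 with quantile normalization and -0.01434 with litter as a fixed block, Trp53 at -0.004507 with quantile normalization and Lamb1 at 0.3706 with litter as a fixed block. Hba-a1 was at 0.06209 and Hbb-bs at 0.0253 on the deposited variance-stabilized values. Leaving out 1 embryo or either pair gave Cryab -0.8829 to 0.3034, Ddx3x -0.06999 to 0.03809, Hba-a1 -0.6111 to 1.083, Hbb-bs -0.6063 to 0.9222, Hdac1 -0.007319 to 0.06394, Id3 -0.03839 to 0.0882, Ier2 -0.03461 to 0.04431, Lamb1 -0.478 to 0.2158, Pim2 -0.05151 to 0.05619, Rhox5 -0.03275 to 0.1067, Trp53 -0.009551 to 0.06582, mt-Nd1 -0.1633 to 0.009454 and the adult blood list a median of -0.6111 to 1.007. Depth limits the genes near the floor of 3 fragments per library, such as Kdm5d in females.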

Other observations

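The motile cilium and later-stage lists were added after Tppp3, Dnaic2 and other cilium genes lower in females in the authors' deposited table had been seen, and the tests on the deposited calls and the splits of counts outside the sex chromosomes were chosen only after the result was seen. Genes of motile cilia were lower in females on average, with overlap between the sexes. Dnaic2, a dynein chain of motile cilia, was at 0 in all 5 females and at 46.2 ± 47.3 normalized counts in males (SD, n = 7), at least 14.7-fold higher in males (adjusted p = 0.0872 by limma). Tppp3, a tubulin-binding protein, was at 108 ± 26.3 (SD, n = 5) and 446 ± 185 (SD, n = 7), with all females below all males (adjusted p = 0.0766 by limma). Of 43 other cilium genes tested, 38 had negative log2 fold changes with a median of -0.62, and none passed singly or when adjusted over the list alone. Their mean level lay between -0.888 and -0.266 in the 5 females, at 0.946, 0.328, 1.1 and 1.04 in male replicates 2, 5, 6 and 7 and at -0.0694, -0.164 and -0.451 in male replicates 1, 3 and 4. Higher in females short of the threshold were Lad1, at 6356 ± 727 (SD, n = 5) and 4461 ± 337 (SD, n = 7; adjusted p = 0.0552 by limma), and Ly6g6c, at 20.8 ± 6.02 (SD, n = 5) and 0 in all males, at least 7.1-fold higher (adjusted p = 0.0826 by limma).

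That cilium genes are lower in female embryos is a hypothesis from these data. A chance choice of the cilium genes first noticed stays open: the list mean differed by -0.9381 (exact permutation p = 0.0152, adjusted p = 0.0303 over 2 lists; camera p = 0.02 with an estimated correlation), but the list holds 0 genes called in the authors' deposited table and was measured in the same 12 embryos, so it excludes nothing and is not independent evidence. More fragments sequenced from male embryos do not account for it, since without the 3 male libraries deeper than every female library the difference was -1.1482, with a pooled SD of 0.4178. A sex difference in developmental progress may contribute and stays open: the later-stage list differed by -0.669 with exact permutation p = 0.201. Over the 12 embryos the lists correlated with r = 0.504 (permutation p = 0.0949) and rho = 0.35 (permutation p = 0.266), and with r = 0.581 without male replicates 6 and 7, the 2 embryos farthest from the median cilium level. A difference among males is open too and was not tested. Male replicates 2, 5, 6 and 7, highest for the cilium list, were also the lowest for the visceral endoderm list, so these 2 patterns rest on the same embryos. The 4 males with the highest cilium levels are among the 5 of the split with 43 genes, but that split was picked as the highest, so the overlap decides nothing.

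The authors' deposited table held 214 calls where limma gave 7. Calls resting on 1 or 2 embryos would often have a weak limma p, and the unadjusted p was 0.05 or more for 0.5% of the 200 deposited calls tested. These calls were chosen by their p in the same 12 embryos, however, so a low limma p could be foreseen and decides little. The 14 not tested were below the filter, above 0 in 2 to 7 embryos and in 2 for 3 of them. Together with the tested calls at 0.05 or more they make up 7% of the 214. Calls resting on 1 or 2 embryos therefore stay open as a cause. Of the 200 deposited calls tested, 0% had the other sign, but both fits used the same 12 embryos, so this could hardly come out otherwise and decides little. Outlier counts replaced in male embryos only do not account for these calls directly, since 0% of the deposited calls had a replaced value. Any effect of the replacement on the calls of other genes was not tested. The difference in the count model and its shrinkage of spread was not tested.

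Other splits of the 12 embryos into 5 and 7 were counted among 100 splits, the real one included. For the 7 genes 3 splits gave as many (highest other 43), for the 2 X-linked genes 2 splits (highest other 3) and for the 9 lists 4 splits (highest other 10), but these counts hold Y-linked genes and Xist, which mark sex and set the real split apart, so they say little of chance elsewhere. Outside the sex chromosomes chance cannot be excluded for the 1 autosomal gene (15 splits, highest other 40) or for the 6 lists (18 splits, highest other 8). For the 1675 autosomal genes at an unadjusted p below 0.05, 4 splits gave as many (highest other 2275, above the real count). With 100 of the 792 splits drawn, that share cannot be told from a 5% limit, so chance stays open there too. For the 1772 genes in all, which include those that mark sex, 4 splits gave as many (highest other 2385). The split with 43 genes set male replicates 2, 3, 5, 6 and 7 against all 5 females with male replicates 1 and 4. It therefore holds part of the sex contrast and is not free of sex. Sex and a difference among males cannot be told apart in it, and a structure among the males was not tested.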
